A study of Mus musculus with 49 samples.

How the data were processed

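RNA of the hippocampus, the cortical structure needed for forming memories, was sequenced from 49 mouse samples of polyadenylated RNA, in 6 groups given by the labels. Endophilin A proteins bend membranes in clathrin-mediated endocytosis and are encoded by Sh3gl2 (endophilin A1), Sh3gl1 (A2) and Sh3gl3 (A3). The age label of the A1A2 double knockouts (DKO, n = 7), their littermate controls (KOWT, n = 7) and separate wild types (WT-DKO, n = 10) was postnatal day 13 to 21. The age label of the A1A2A3 triple knockouts (TKO, n = 9), their littermate controls (KOWTKO, n = 8) and separate wild types (WT-TKO, n = 8) was postnatal day 0. The growth label of every sample gave newborn mice, which conflicts with the age label of the 3 older groups. The age label was used. Nothing in the labels says that samples of a group came from separate animals, so p-values measure the spread between these samples, which may be technical.

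Total RNA was extracted with 1 of 2 column kits, which the labels do not tie to samples, and libraries were prepared with a TruSeq RNA kit that does not mark strand. Per the submitters' processing notes, CASAVA 1.8.2, STAR 2.3.0e and DESeq2 (no version given) were used with mouse build mm10. The read counter and the gene annotation are not given in the sources used here. The deposited count table held the authors' whole-number read counts per Ensembl gene, not normalized, with 38355 genes. It also held 5 lines that name no gene, which were left out of library sizes and tests. Of the reads counted on genes, without a feature or as ambiguous, those without a feature were 8.89% to 17.5% per library and the ambiguous ones 1.57% to 1.92%. Alignments that were not unique came to 38.4 to 86.8 per 100 reads on genes. The authors' deposited tables of 4 comparisons gave log2 fold changes, and p-values before and after adjustment, per the file headers. Values from them are named as the authors' wherever they are printed. Reads on genes ran from 13.1 M to 57.0 M (mega) per library, and 2.82% to 5.78% of them fell on the 10 most abundant genes. No pair of libraries of a group agreed within sampling noise in a chi-square comparison over genes with at least 20 reads.

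Symbols, positions and biotypes came from the GENCODE M21 annotation of GRCm38, the assembly that mm10 denotes, matched by Ensembl identifier. Of the 38355 genes, 36602 matched, 174 were named only from the authors' tables, and 1579 stayed without a name. Of the genes listed by both sources, 99.98% had overlapping positions. Reads of overlapping genes cannot be told apart by strand with this kit.

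Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes passing filterByExpr were kept, libraries were scaled by TMM, dispersions and the quasi-likelihood fit were robust, and the 3 groups of an age shared 1 fit with group means only. Each of 6 comparisons was a contrast tested with the quasi-likelihood test. P-values were adjusted by the Benjamini-Hochberg method and genes with an adjusted p under 0.05 were called. CPM are counts per M reads on genes, scaled by TMM. Errors of CPM are SDs over libraries and errors of log2 fold changes are SEs. Whether effects differed between the ages was tested as a difference of log2 fold changes over all 49 libraries. Overlaps of calls between ages, whose comparisons share no library, were tested with one-sided Fisher's exact tests. The 33 gene lists were tested with camera in limma 3.58.1 at its preset inter-gene correlation of 0.01, adjusted over the lists of a comparison, with an estimated correlation and fry as alternatives. Members were also adjusted over the list alone. Lists on FoxO targets and ubiquitin ligases were drawn up knowing what this study is about, so their direction is not independent evidence.

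The groups, tests, gene lists and alternatives were fixed before the data were examined. So was the rule for named genes. It took the 3 targeted genes, the 6 called genes that rose most and the 6 that fell most among genes with a mean log2 CPM of at least 1, the 3 members with the smallest p of each leading list, Fbxo32 and Foxo3. It also took the 10 genes with the smallest largest p among those called the same way in all 4 comparisons of a mutant. A few genes taken by this rule are not reported here. How many lists counted as leading, 5 for a mutant and 3 for a pair of control groups, was set after the p-values of the lists were seen. The number for mutants was set partly so that the FoxO list entered the comparison of TKO with KOWTKO.

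The procedure was tested on simulated counts with the means, library sizes and dispersions of the real genes and 200 changed genes. This test was run after the first results on the real counts were seen. In simulated DKO versus KOWT (16014 genes), the quasi-likelihood test recovered 80 of 100 genes changed 1.5-fold and 97 of 100 changed 2-fold, with 4.84% of calls false. In simulated TKO versus KOWTKO (15618 genes), it recovered 83 and 96 of 100, with 3.24% false, and DESeq2 (15715 genes) recovered 87 and 97 with 10.7% false.

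The alternatives fixed beforehand were DESeq2 size factors, no filter on low counts, DESeq2 1.42.0, limma-voom, only the compared groups in the fit, the replicate number as a block, 1 surrogate variable (sva 3.50.0), genes over 10 Mb from the targeted genes, a list mean as a proxy of age (myelin genes in the older samples, proliferation genes in the newborn ones) and leaving out each library in turn. After the data were seen, 4 more were added. These left out 7 libraries that stood apart, took the Xist level or the mean of choroid plexus genes as a covariate, or counted only protein-coding genes. The 7 libraries were chosen by their levels of Sh3gl3, of Sh3gl1 and Stap2, or of myelin and sex-linked genes. Sh3gl1, Sh3gl3, Stap2, Mpnd and Mbp were therefore not tested again as named genes without them. Myelin genes served to choose WT-TKO replicate 8, so results of the myelin list without that library are not independent evidence. Figures were drawn with matplotlib 3.10.9.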

Results

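The transcriptome of mouse hippocampus was measured in 49 samples that lacked or carried endophilin A genes, at 2 ages. Reads on genes had medians of 21.6 M (mega) in double-knockout (DKO), 25.8 M in their littermate (KOWT) and 22.4 M in wild-type (WT-DKO) libraries at postnatal day 13 to 21. At postnatal day 0 the medians were 22.2 M in triple-knockout (TKO), 24.5 M in littermate (KOWTKO) and 18.4 M in wild-type (WT-TKO) libraries. Over both ages, single libraries held 13.1 M to 57.0 M.

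The targeted genes were examined first. Sh3gl1 (ENSMUSG00000003200, mm10 chromosome 17, 56016750 to 56036635) stood at 0.767 ± 0.274 CPM in DKO (SD, n = 7) and 0.856 ± 0.297 in TKO (n = 9). It reached 57.7 ± 4.36 in KOWT (n = 7), 56.3 ± 2.45 in WT-DKO (n = 10), 69.4 ± 15.0 in KOWTKO (n = 8) and 69.5 ± 4.16 in WT-TKO (n = 8). Sh3gl2 (ENSMUSG00000028488, chromosome 4, 85205126 to 85639195) was low in the mutants and also in the libraries labelled littermate controls. It measured 39.0 ± 2.04 CPM in DKO, 38.4 ± 1.10 in KOWT and 418 ± 22.6 in WT-DKO, and 19.5 ± 6.95 in TKO, 18.5 ± 6.54 in KOWTKO and 201 ± 21.1 in WT-TKO. Sh3gl3 (ENSMUSG00000030638, chromosome 7, 82173840 to 82307419) was nearly absent from TKO (0.238 ± 0.114 CPM) and from the libraries labelled KOWTKO (0.250 ± 0.126), against 59.9 ± 4.32 in WT-TKO. The comparisons with littermates therefore set loss of Sh3gl1 against its presence in samples that were all low in Sh3gl2, and at day 0 in Sh3gl3 as well. In the older samples Sh3gl3 varied within groups, with 46.2 ± 27.5 CPM in DKO, 42.1 ± 27.0 in KOWT and 50.6 ± 6.44 in WT-DKO. It lay at 15.1, 12.6 and 12.3 CPM in KOWT replicates 4, 5 and 6 and at 6.46 and 6.31 in DKO replicates 5 and 6. In the library labelled KOWTKO replicate 3, Sh3gl1 stood at 35.0 CPM. The labels give no genotype that sets these libraries apart, so whether they were mixed or of another genotype is open, and the means of their groups include them. Without strand, reads of overlapping genes cannot be told apart, which leaves the levels of Sh3gl2 (with Adamtsl1), Sh3gl1 (with Mpnd), Cyp51, Dio2, Gfap, Sult1a1, Plin4, Irf9, Cx3cr1, Shank1, Shank3, Grin1, Scand1, Mir5105, Rpe, Hist3h2a, Serpina3m and BC002163 uncertain to that extent.

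**Figure D1:**
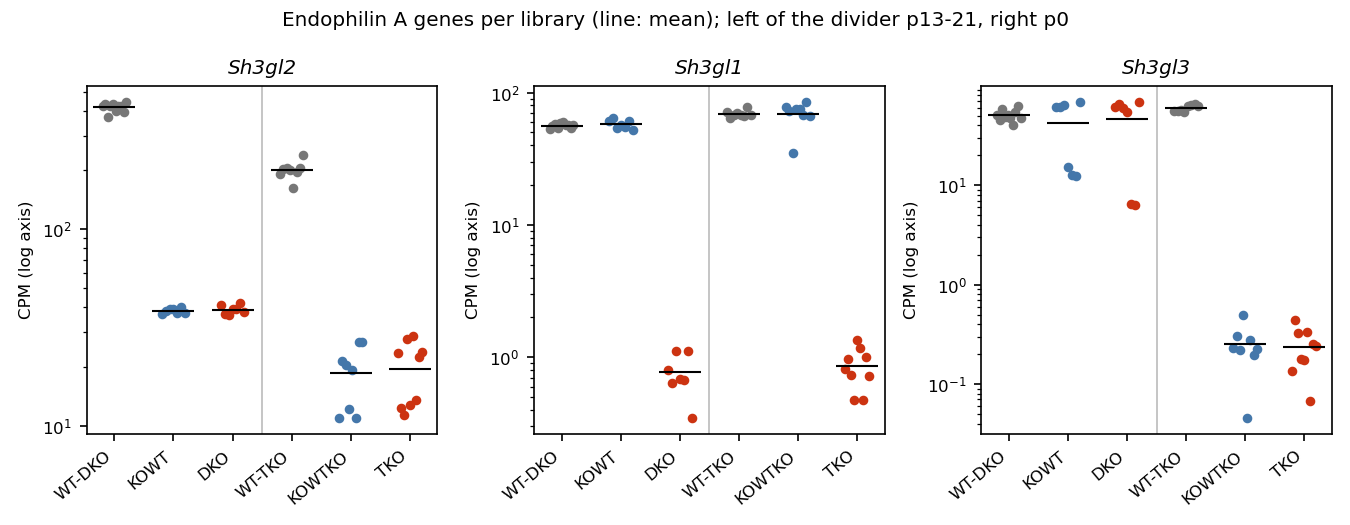
Normalised read counts (CPM, log axis) of Sh3gl2, Sh3gl1 and Sh3gl3 in each library (points) with the group mean (line); the divider separates day 13 to 21 (left) from day 0 (right). Sh3gl1 is below 2 CPM in DKO and TKO only, while Sh3gl2 is low in both mutants and both littermate groups.

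The next comparison set older DKO against littermates (DKO, n = 7; KOWT, n = 7), and thus loss of Sh3gl1 against its presence in samples that were all low in Sh3gl2. Genes that neurons switch on when active were lower in DKO. Arc, which acts at synapses, fell from 167 ± 83.2 to 44.9 ± 30.4 CPM (log2 fold change -1.89 ± 0.37). The transcription factor genes Fosb and Fos fell by 1.98 ± 0.35 and 1.94 ± 0.39 on the log2 scale. Fosl2 (-0.72 ± 0.10), the neurotrophin gene Bdnf (-0.45 ± 0.08) and the synaptic scaffold gene Homer1 (-0.59 ± 0.10) fell as well. Of 31 activity-regulated genes, 21 fell, 0 rose and 10 were not called, and 22 fell when adjusted over the list alone (camera adjusted p = 6.03e-13; adjusted p = 0.11 with an estimated correlation). Beside Sh3gl1 (-6.23 ± 0.11, edgeR quasi-likelihood adjusted p = 3.2e-25, below all KOWT libraries in 7 of 7), the largest changes lay next to it. Stap2, an adaptor protein gene at 55997077 to 56005584 on chromosome 17, rose from 2.06 ± 0.345 to 25.4 ± 3.21 CPM. Mpnd, at 56005711 to 56016790, fell from 78.0 ± 8.24 to 14.1 ± 2.07 CPM, and its annotated exons share 41 bases with those of Sh3gl1, over which reads of the pair cannot be told apart by strand. Other genes that rose most were Etnppl (1.79 ± 0.40), the collagen gene Col6a1 (1.64 ± 0.27), Arhgap36 (1.73 ± 0.27), Lsp1 (1.52 ± 0.17) and Slc2a4, the insulin-responsive glucose transporter (1.39 ± 0.24). Stbd1, a glycogen-binding protein gene, fell by 1.79 ± 0.40. Of the 5 endophilin genes, Sh3gl1 alone was called, so that the list had a median of 0.02 but a mean of -1.22 and tested lower (camera adjusted p = 2.15e-30; adjusted p = 2.35e-09 with an estimated correlation). This list holds the targeted genes, so its fall follows from the design. Of 13 meningeal and fibroblast genes, which mark tissue outside the hippocampus, 5 rose, 6 when adjusted over the list alone (camera adjusted p = 0.00671; adjusted p = 0.647 with an estimated correlation), a call of the list that ended without the libraries low in Sh3gl3. Of 20 hippocampal excitatory neuron genes, 4 fell and 0 rose, also when adjusted over the list alone (camera adjusted p = 0.0436; adjusted p = 0.703 with an estimated correlation), the call of the list ended by fry, and 2 fell without the libraries low in Sh3gl3.

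Other groups of genes were lower in DKO than in KOWT too. Of 20 oligodendrocyte and myelin genes, 7 fell and 0 rose, 10 falling when adjusted over the list alone (camera adjusted p = 2.11e-05; adjusted p = 0.654 with an estimated correlation). The mean of the list, in log2 CPM, was 5.71 and 6.01 in DKO replicates 5 and 6, which were low in Sh3gl3, 6.83 to 7.33 in the other DKO libraries and 6.78 to 7.84 in KOWT, and 1 of the 20 fell without the libraries low in Sh3gl3. In DKO versus WT-DKO 3 of the 20 fell, also when adjusted over the list alone (camera adjusted p = 0.111). Transferrin (Trf, -1.20 ± 0.27) and the connexin gene Gjb1 (-1.09 ± 0.30) were among those that fell in DKO versus KOWT, and the call of Gjb1 was lost without the libraries that stood apart (-0.86). Of 20 cholesterol synthesis genes, 7 fell, including the enzymes Msmo1 (-0.58 ± 0.09) and Cyp51 (-0.41 ± 0.09), and 11 fell when adjusted over the list alone (camera adjusted p = 0.000367; adjusted p = 0.5 with an estimated correlation). Calls of Cyp51 (-0.24) and Aldh1a1 (-0.27) ended with the myelin mean as a proxy of age. Of 22 genes of the integrated stress and unfolded protein responses, 11 fell and 1 rose, with 12 and 1 when adjusted over the list alone (camera adjusted p = 0.000616; adjusted p = 0.11 with an estimated correlation). Without the libraries low in Sh3gl3, 5 of the 22 fell and 0 rose, with the list still called (camera adjusted p = 0.000111). The endoplasmic reticulum gene Sdf2l1 (-0.76 ± 0.14) and the transcription factor genes Xbp1 (-0.39 ± 0.08) and Atf4 (-0.28 ± 0.06) fell. Of 14 thyroid hormone response genes, 4 fell, with 5 when adjusted over the list alone (camera adjusted p = 0.00671; adjusted p = 0.11 with an estimated correlation). They included Dio2, which makes active thyroid hormone (-0.74 ± 0.14), Gpr155 (-0.39 ± 0.07) and Aldh1a1 (-0.38 ± 0.09). Of 34 ubiquitin ligase genes, a list chosen knowing the study topic, 5 rose and 5 fell, also when adjusted over the list alone (camera adjusted p = 0.931), and 1 rose and 1 fell without the libraries low in Sh3gl3. Fbxo32, a muscle-atrophy ubiquitin ligase gene, was at 18.8 ± 3.39 CPM in DKO and 18.5 ± 2.84 in KOWT (log2 fold change 0.03 ± 0.12), and Foxo3 at 65.7 ± 2.52 and 67.9 ± 2.96. With the myelin mean as a proxy of age, Fbxo32 was called higher in DKO (0.31).

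Of 16114 genes tested in DKO versus KOWT, 1646 rose and 1701 fell, 175 of them at least 2-fold. The authors' deposited table listed 4831 at an adjusted p under 0.05. The 3347 calls became 2228 with only these 2 groups in the fit, 2028 with the age proxy and 1082 without the 5 DKO and KOWT libraries low in Sh3gl3. Of those 1082 calls, 1027 were among the 3347.

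**Figure D2:**
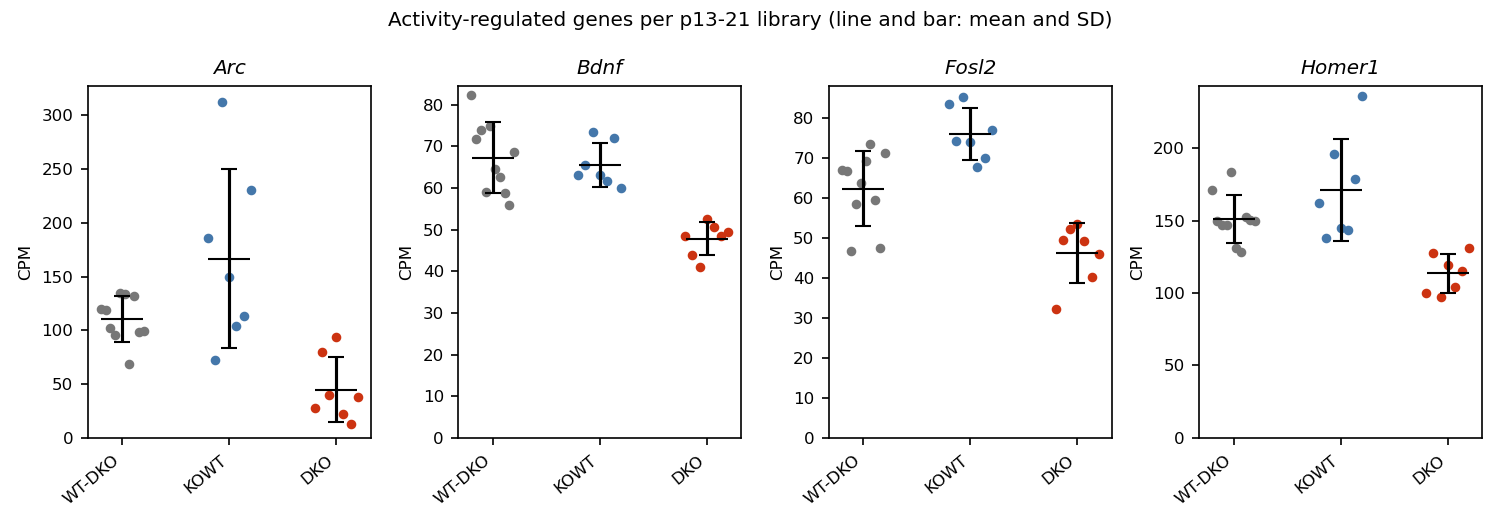
Normalised read counts (CPM) of Arc, Bdnf, Fosl2 and Homer1 in each library at day 13 to 21 (points), with group mean and SD (line and bar). Bdnf averages 47.8 in DKO, 65.6 in KOWT and 67.3 in WT-DKO.

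Against separate wild types (DKO, n = 7; WT-DKO, n = 10), interferon and cholesterol synthesis genes were lower and glucocorticoid response genes higher in DKO. Sh3gl2 (-3.42 ± 0.05) and Sh3gl1 (-6.19 ± 0.11) fell and Sh3gl3 was not called (-0.13 ± 0.44). Of 20 cholesterol synthesis genes, 14 fell and 0 rose, 17 falling when adjusted over the list alone (camera adjusted p = 1.1e-06; adjusted p = 0.362 with an estimated correlation), such as Msmo1 (-0.59 ± 0.08) and Cyp51 (-0.53 ± 0.08). Without the libraries that stood apart, 9 of the 20 fell, with the list still called (camera adjusted p = 3.13e-07). Of 20 interferon response genes, 11 fell, 16 when adjusted over the list alone (camera adjusted p = 1.51e-06; adjusted p = 0.366 with an estimated correlation), with Isg15 at -1.76 ± 0.25 and B2m, the light chain of class I histocompatibility proteins, at -0.66 ± 0.12. Of 19 glucocorticoid response genes, 9 rose and 0 fell, 12 rising when adjusted over the list alone (camera adjusted p = 3.28e-06; adjusted p = 0.362 with an estimated correlation). The kinase gene Sgk1 rose from 66.7 ± 8.55 to 147 ± 42.1 CPM, Nfkbia by 0.67 ± 0.09 and Sult1a1 by 1.18 ± 0.18 on the log2 scale.

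Of 31 activity-regulated genes, 16 fell and 2 rose in DKO versus WT-DKO, 20 and 2 when adjusted over the list alone (camera adjusted p = 3.44e-06; adjusted p = 0.362 with an estimated correlation), among them Bdnf (-0.49 ± 0.07) and the transcription factor genes Egr3 (-0.68 ± 0.11) and Egr4 (-0.83 ± 0.15). Of 22 reactive astrocyte genes, 9 rose and 1 fell, also when adjusted over the list alone (camera adjusted p = 0.00704; adjusted p = 0.362 with an estimated correlation). Gfap, the astrocyte filament gene, rose from 293 ± 29.4 to 528 ± 162 CPM and Aspg by 1.29 ± 0.20, while Iigp1, an interferon-induced GTPase gene, fell by 1.72 ± 0.23 on the log2 scale. Of 15 astrocyte markers, 1 rose and 4 fell, 1 and 5 when adjusted over the list alone (camera adjusted p = 0.258), and 1 rose and 2 fell without the libraries that stood apart. Of 22 microglia markers, 8 fell and 1 rose, also when adjusted over the list alone (camera adjusted p = 0.0321; adjusted p = 0.597 with an estimated correlation), a call of the list that ended without the libraries that stood apart, where 4 fell and 1 rose. Of 20 proliferation genes, 5 fell, 7 when adjusted over the list alone (camera adjusted p = 0.00704; adjusted p = 0.597 with an estimated correlation). Other genes changed most by fold. Stap2 rose (3.51 ± 0.10) and Mpnd (-2.35 ± 0.08), the beta-globin gene Hbb-bt (-2.37 ± 0.43), the iodotyrosine deiodinase gene Iyd (-2.22 ± 0.30) and the respiratory chain gene Ndufs5 (-2.10 ± 0.59) fell. In WT-DKO replicate 3, Ndufs5 was low and the pseudogene BC002163 high, and whether reads shifted between them was not tested. The pseudogenes Rps13-ps1 (5.78 ± 2.98 against 0.0262 ± 0.0295 CPM), Rps15a-ps8 (3.68 ± 1.89 against 0.0186 ± 0.0271) and Wsb2-ps (2.73 ± 2.58 against 0.260 ± 0.121) were higher, as were the serpin genes Serpina3m (7.86 ± 5.22 against 0.360 ± 1.07) and Serpina3f (5.01 ± 3.03 against 0.297 ± 0.783). All 5 have near-identical copies, so their levels are uncertain, and without WT-DKO replicate 4 the log2 fold changes of Serpina3m and Serpina3f were 8.72 and 6.77. Fbxo32 (0.15 ± 0.11) and Foxo3 (-0.08 ± 0.05) were not called, but Fbxo32 was called with the age proxy (0.29). Of 16114 genes, 2115 rose and 2088 fell, 327 at least 2-fold; the authors' deposited table listed 5500, and 2971 were called without the libraries that stood apart.

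The littermates themselves differed from the separate wild types (KOWT, n = 7; WT-DKO, n = 10). Besides Sh3gl2 (-3.44 ± 0.05), glucocorticoid response genes were higher and interferon genes lower in KOWT, while Sh3gl1 (0.03 ± 0.07) and Sh3gl3 (-0.27 ± 0.44) were not called. Of 19 glucocorticoid genes, 12 rose and 0 fell, 16 rising when adjusted over the list alone (camera adjusted p = 1.27e-16; adjusted p = 0.0438 with an estimated correlation). Nfkbia (0.55 ± 0.09), Tsc22d3, a glucocorticoid-induced regulator (0.70 ± 0.12), and the lipid droplet gene Plin4 (2.22 ± 0.38) rose. Of 20 interferon genes, 12 fell, 17 when adjusted over the list alone (camera adjusted p = 9.91e-13; adjusted p = 0.188 with an estimated correlation), with Gbp3 at -1.10 ± 0.21, Ifit3b at -1.29 ± 0.27 and Lgals3bp at -0.79 ± 0.16. Without the libraries that stood apart, 6 of the 20 fell, with the list still called (camera adjusted p = 7.6e-09). Of 22 microglia markers, 3 fell, 10 when adjusted over the list alone (camera adjusted p = 0.000149; adjusted p = 0.247 with an estimated correlation): Itgam (-0.47 ± 0.11), Cx3cr1 (-0.34 ± 0.08) and Fcer1g (-0.31 ± 0.09), whose call ended when any of 12 of the 17 libraries was left out and under 6 other settings (-0.32 to -0.26). Of 31 activity-regulated genes, 2 rose in KOWT, 5 when adjusted over the list alone (camera adjusted p = 0.00365; adjusted p = 0.548 with an estimated correlation), and 6 rose without the libraries that stood apart. Of 20 oligodendrocyte and myelin genes none was called, with a median of 0.33 (camera adjusted p = 0.000515; adjusted p = 0.673 with an estimated correlation). By fry, the calls of the activity-regulated and myelin lists ended.

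Iyd (-1.92 ± 0.29), Hbb-bt (-1.61 ± 0.40), Eps8l1 (-1.56 ± 0.17), the endothelial lipase gene Lipg (-1.46 ± 0.19) and the interferon-induced Oasl2 (-1.43 ± 0.30) fell most in KOWT. The call of Hbb-bt ended without KOWT replicate 3 or 4 and that of Ifit3b without the libraries that stood apart (-1.23). Rps15a-ps8 (3.51 ± 2.41 CPM), Rps13-ps1 (4.22 ± 2.97), Wsb2-ps (3.69 ± 1.62), Serpina3m (7.48 ± 3.61), Serpina3f (4.35 ± 2.18) and the pseudogene BC002163 (14.6 ± 5.10 against 1.63 ± 3.29) were higher in KOWT. With limma-voom, Rps15a-ps8 (5.21), Rps13-ps1 (5.17), Serpina3m (6.28) and Serpina3f (4.87) were not called. Without WT-DKO replicate 4, Serpina3m and Serpina3f had log2 fold changes of 8.61 and 6.52, and without replicate 3 BC002163 had 4.67. Fbxo32 (0.12 ± 0.11) and Foxo3 (-0.03 ± 0.05) were not called. Of 16114 genes, 375 rose and 336 fell, 148 at least 2-fold. The 711 calls became 470 without KOWT replicate 3, and 566 without the libraries that stood apart.

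At birth, TKO were compared with littermates (TKO, n = 9; KOWTKO, n = 8), which set loss of Sh3gl1 against its presence in samples that were all low in Sh3gl2 and Sh3gl3. Fbxo32 rose from 10.2 ± 1.17 to 16.9 ± 2.99 CPM (log2 fold change 0.73 ± 0.10, edgeR quasi-likelihood adjusted p = 0.000155), with all 9 TKO libraries above all 8 KOWTKO libraries. Of 28 FoxO factors and targets, 3 rose and 0 fell, and 7 rose and 3 fell when adjusted over the list alone (camera adjusted p = 0.0135; adjusted p = 0.518 with an estimated correlation), in a list chosen knowing the study topic and thus not independent evidence. The others were Ccng2, an unconventional cyclin gene (0.38 ± 0.07), and Foxo3 (0.20 ± 0.05), whose call ended without KOWTKO replicate 2 or TKO replicate 1 or 8, with no filter on low counts (0.20) and with only these 2 groups (0.19). Of 32 ubiquitin ligase genes 1 rose and 1 fell, also when adjusted over the list alone (camera adjusted p = 0.76). Hif3a, of the hypoxia-inducible factor family, rose from 2.76 ± 0.747 to 8.37 ± 3.70 CPM. The ceramidase gene Acer2 (1.24 ± 0.16), the potassium channel gene Kcna5 (1.20 ± 0.28), Fam107a (1.06 ± 0.25) and the amino acid transporter gene Slc7a3 (1.04 ± 0.20) rose. Sh3gl1 (-6.31 ± 0.16) and Mpnd (-2.25 ± 0.10) fell and Stap2 rose (3.21 ± 0.32), while Sh3gl2 (0.08 ± 0.21) and Sh3gl3 (-0.02 ± 0.28) were not called.

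**Figure D3:**
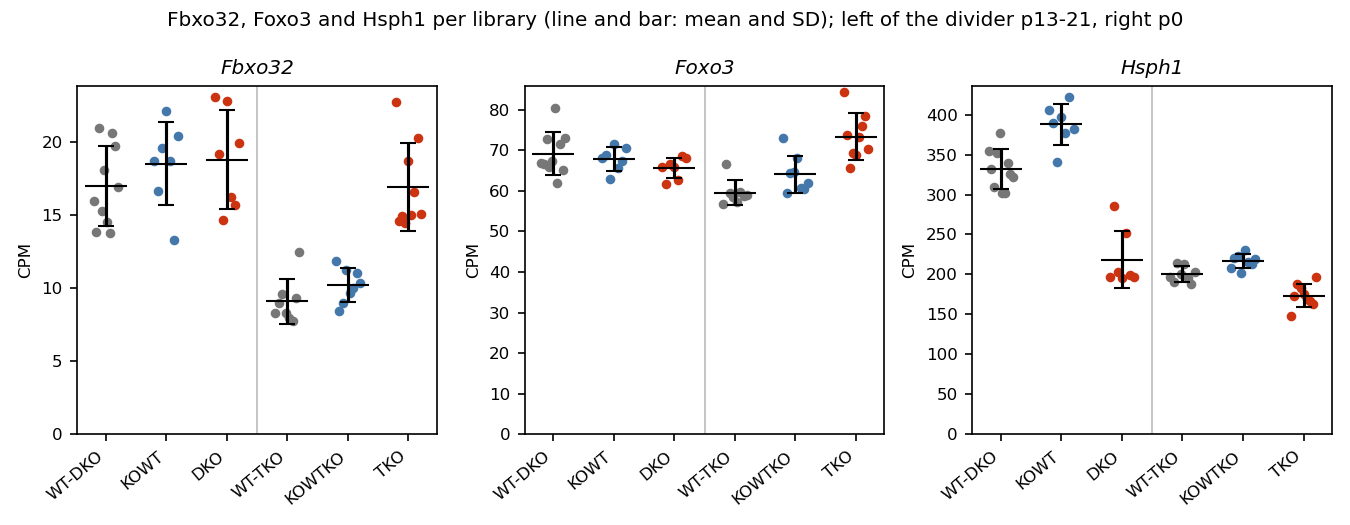
Normalised read counts (CPM) of Fbxo32, Foxo3 and Hsph1 in each library (points) with group mean and SD (line and bar); the divider separates day 13 to 21 (left) from day 0 (right). Fbxo32 averages 16.9 in TKO against 10.2 in KOWTKO and 9.09 in WT-TKO.

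Other lists were called in TKO versus KOWTKO with few called members. Neuropeptide Y (Npy, -0.50 ± 0.10) and the interneuron transcription factor gene Lhx6 (-0.21 ± 0.06) were the 2 of 18 inhibitory neuron genes that fell, also when adjusted over the list alone (camera adjusted p = 0.0114; adjusted p = 0.376 with an estimated correlation). Somatostatin (Sst) measured -0.33 ± 0.12. Npy and Pnoc (-0.35 ± 0.07) were the 2 of 14 seizure-regulated neuropeptide genes that fell, 5 falling when adjusted over the list alone (camera adjusted p = 0.0127; adjusted p = 0.472 with an estimated correlation), and Crh measured -0.82 ± 0.25 and was called under 5 other settings (-0.84 to -0.81). The scaffold genes Shank3 (-0.51 ± 0.10) and Shank1 (-0.43 ± 0.12) were the 2 of 29 postsynaptic genes that fell, 3 falling when adjusted over the list alone (camera adjusted p = 0.0114; adjusted p = 0.535 with an estimated correlation), and Grin1 measured -0.23 ± 0.07, called with DESeq2 (-0.23). Without KOWTKO replicate 3 and WT-TKO replicate 8, 1 of the 29 fell. Of 28 activity-regulated genes, 1 rose and 0 fell, also when adjusted over the list alone (camera adjusted p = 0.339). Of 17 glucocorticoid genes, only the sulfotransferase gene Sult1a1 rose (1.87 ± 0.30), 3 rising when adjusted over the list alone (camera adjusted p = 0.000437; adjusted p = 0.421 with an estimated correlation), with Cdkn1a at 0.39 ± 0.12, called under 5 other settings (0.39 to 0.41), and Pdk4 at 0.44 ± 0.15, called with DESeq2 (0.44). Among 13 choroid plexus genes (median 0.47; camera adjusted p = 0.0305; adjusted p = 0.724 with an estimated correlation) and 13 meningeal genes (median -0.36; camera adjusted p = 0.0272; adjusted p = 0.728 with an estimated correlation) none was called, over all genes or adjusted over the list alone, and the call of the meningeal list ended without KOWTKO replicate 3 and WT-TKO replicate 8. Nor was any of 19 excitatory neuron genes, also when adjusted over the list alone (median -0.13; camera adjusted p = 0.0373; adjusted p = 0.518 with an estimated correlation). Fry called 6 lists where camera called 13, and those whose calls ended were the FoxO, neuropeptide, postsynaptic, synaptic vesicle, excitatory neuron, choroid plexus and meningeal lists. Scand1 (-2.39 ± 0.54), Mir5105 (-1.68 ± 0.42), C1qtnf4 (-1.18 ± 0.30) and Pcsk1n, which encodes a peptide-processing inhibitor (-1.16 ± 0.32), fell.

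Several of these rested on single libraries. Scand1 stood at 21.7 CPM in KOWTKO replicate 1 against 4.97 ± 7.04 in its group, and without it the log2 fold changes were -1.43 for Scand1 and -0.74 for Pcsk1n. Calls of Mir5105 ended without KOWTKO replicate 1 or 5, of C1qtnf4 without KOWTKO replicate 1 or 5 or TKO replicate 8, of Lhx6 without KOWTKO replicate 4 or TKO replicate 5, 6 or 7, of Pcsk1n without any of 9 libraries and of Shank1 without any of 11. With limma-voom, Scand1 (-1.64), Mir5105 (-1.26), C1qtnf4 (-0.94) and Pcsk1n (-0.95) were not called, nor were C1qtnf4 (-1.18), Pcsk1n (-1.16), Shank1 (-0.43) and Lhx6 (-0.21) with no filter. Calls of Mir5105 (-1.34), Pcsk1n (-1.11) and Shank1 (-0.31) also ended with the choroid plexus mean as a covariate, and those of Pcsk1n (-1.17), Shank1 (-0.43) and Lhx6 (-0.21) with only these 2 groups. The call of Shank1 (-0.41) ended without KOWTKO replicate 3 and WT-TKO replicate 8 as well. Of 15715 genes tested in TKO versus KOWTKO, 379 rose and 421 fell, 32 at least 2-fold, and the authors' deposited table listed 1262. The 800 calls became 483 with no filter on low counts, 1306 with DESeq2 and 621 without KOWTKO replicate 3 and WT-TKO replicate 8. They ranged from 330 without KOWTKO replicate 5 to 1444 without KOWTKO replicate 7, and fell to 484, 425, 471 and 465 without KOWTKO replicates 1, 2 and 3 and TKO replicate 8. Of the newborn libraries, KOWTKO replicate 7 had the most reads without a feature (15.1%). It also had the most alignments that were not unique (86.8 per 100 reads on genes), yet was not among the libraries left out together.

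Against separate wild types (TKO, n = 9; WT-TKO, n = 8), interferon, microglial and meningeal genes were lower in TKO. Sh3gl3 (-7.86 ± 0.16), Sh3gl1 (-6.32 ± 0.16) and Sh3gl2 (-3.36 ± 0.21) fell. Of 17 interferon genes, 15 fell and 0 rose, also when adjusted over the list alone (camera adjusted p = 7.26e-11; adjusted p = 0.294 with an estimated correlation), with B2m at -0.91 ± 0.13, Ifi27 at -1.17 ± 0.18 and Isg15 at -1.83 ± 0.33. Of 22 microglia markers, 12 fell, 17 when adjusted over the list alone (camera adjusted p = 1.9e-06; adjusted p = 0.387 with an estimated correlation), such as Itgam (-0.92 ± 0.17), Tmem119 (-1.24 ± 0.25) and Aif1 (-1.43 ± 0.30). Of 13 meningeal and fibroblast genes, 12 fell, also when adjusted over the list alone (camera adjusted p = 3.55e-06; adjusted p = 0.387 with an estimated correlation), including the collagen gene Col1a1 (-2.53 ± 0.57), the retinoic acid enzyme gene Aldh1a2 (-2.66 ± 0.61) and the transporter gene Slc22a6 (-3.17 ± 0.78). Meninges lie outside the hippocampus, and Ptgds, which they express strongly, ranged from 1.56 to 147 CPM among WT-TKO libraries. Of 13 choroid plexus genes, 4 fell, 8 when adjusted over the list alone (camera adjusted p = 0.0206; adjusted p = 0.534 with an estimated correlation), and the mean of the list, in log2 CPM, was 0.909 ± 0.416 in TKO and 1.57 ± 0.736 in WT-TKO.

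Of 28 FoxO factors and targets, 10 rose and 1 fell in TKO versus WT-TKO, 11 and 2 when adjusted over the list alone (camera adjusted p = 0.000748; adjusted p = 0.387 with an estimated correlation), in the list chosen knowing the study topic. Fbxo32 rose from 9.09 ± 1.52 to 16.9 ± 2.99 CPM (0.91 ± 0.10), Foxo3 by 0.30 ± 0.05 and the ubiquitin ligase gene Fbxo21 by 0.23 ± 0.04 on the log2 scale. Of 14 seizure-regulated neuropeptide genes, 7 fell and 1 rose, also when adjusted over the list alone (camera adjusted p = 0.00408; adjusted p = 0.387 with an estimated correlation), with Pdyn at -1.54 ± 0.19, Npy at -0.71 ± 0.10 and Sst at -0.66 ± 0.12. Stap2 (3.42 ± 0.32), the renin gene Ren1 (3.39 ± 0.22), Acer2 (1.90 ± 0.17) and the immunoglobulin E receptor gene Fcer2a (1.65 ± 0.29) rose. Rps13-ps1 (7.74 ± 2.96 against 0.168 ± 0.452 CPM) and Rps15a-ps8 (6.51 ± 2.48 against 0.211 ± 0.529) were higher. Ptgds (-4.01 ± 0.77), Tpm3-rs7 (-3.58 ± 0.81) and the tight junction gene Cldn11 (-3.46 ± 0.72) fell, but Ptgds and Tpm3-rs7 were not called by limma-voom (-2.64 and -1.87) and Cldn11 was at -2.07 without WT-TKO replicate 8. That library held 247 CPM of the myelin gene Mbp, against 26.6 to 33.1 in the other WT-TKO libraries. Of 15 oligodendrocyte and myelin genes 4 fell, 11 when adjusted over the list alone (camera adjusted p = 0.0307; adjusted p = 0.759 with an estimated correlation), and the call of the list ended by fry. Without WT-TKO replicate 8 and KOWTKO replicate 3, 2 fell and 1 rose, with a median of 0.0085, but replicate 8 was chosen by its myelin genes. Of 15715 genes, 1704 rose and 1891 fell, 234 at least 2-fold; the authors' deposited table listed 4051, and 3848 were called without WT-TKO replicate 8 and KOWTKO replicate 3.

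The newborn littermates also differed from the separate wild types (KOWTKO, n = 8; WT-TKO, n = 8). Sh3gl3 (-7.83 ± 0.17) and Sh3gl2 (-3.45 ± 0.22) fell and Sh3gl1 was not called (-0.0026 ± 0.12). Of 22 microglia markers, 16 fell and 0 rose, 19 falling when adjusted over the list alone (camera adjusted p = 3.88e-09; adjusted p = 0.315 with an estimated correlation), with the microglial receptor gene Trem2 at -0.72 ± 0.13, Laptm5 at -0.47 ± 0.09 and Fcer1g at -0.73 ± 0.14. Of 17 interferon genes, 9 fell, 13 when adjusted over the list alone (camera adjusted p = 3.98e-07; adjusted p = 0.416 with an estimated correlation), among them Irf9 (-0.62 ± 0.09), B2m (-0.85 ± 0.13) and Lgals3bp (-1.20 ± 0.22). Without KOWTKO replicate 3 and WT-TKO replicate 8, 5 of the 17 fell, with the list still called (camera adjusted p = 7.96e-06). Of 13 genes of the choroid plexus, the tissue that makes cerebrospinal fluid, 10 fell, 12 when adjusted over the list alone (camera adjusted p = 2.24e-05; adjusted p = 0.416 with an estimated correlation). Transthyretin (Ttr) went from 213 ± 356 to 14.3 ± 6.87 CPM, Slc4a5 measured -2.39 ± 0.49 and Cldn2 -1.32 ± 0.30, and the last 2 measured -1.48 and -0.85 without WT-TKO replicate 7, which held 1081 CPM of Ttr. Of 13 meningeal genes 4 fell, 7 when adjusted over the list alone (camera adjusted p = 0.00523; adjusted p = 0.727 with an estimated correlation), and the call of the list ended by fry.

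Ren1 (2.99 ± 0.23) and the mechanosensitive channel gene Piezo2 (1.74 ± 0.31) rose in KOWTKO, and the pseudogenes Rps13-ps1 (6.08 ± 5.48 CPM) and Rps15a-ps8 (5.37 ± 4.86) were higher, but not called by limma-voom (5.31 and 4.96). The non-coding RNA gene Rn7sk (2.47 ± 0.80) and Scand1 (1.83 ± 0.54) were called, but without KOWTKO replicate 7 Rn7sk was at 0.68, and without KOWTKO replicate 1 Scand1 was at 0.87, neither called. The call of Rn7sk also ended without WT-TKO replicate 2, 3, 4, 5 or 6 and under other settings, among them DESeq2 (0.62) and limma-voom (1.08), and that of Scand1 with limma-voom (1.09), only these 2 groups (1.83) and the choroid plexus mean (1.52). Ptgds (-3.84 ± 0.79), Rpl3-ps1 (-3.64 ± 0.86) and Tpm3-rs7 (-3.54 ± 0.84) fell, but were not called by limma-voom (-2.38, -1.90 and -1.78). Fbxo32 (0.17 ± 0.11) and Foxo3 (0.11 ± 0.05) were not called. Of 15715 genes, 1645 rose and 1643 fell, 194 at least 2-fold, and 3502 were called without KOWTKO replicate 3 and WT-TKO replicate 8.

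**Figure D4:**
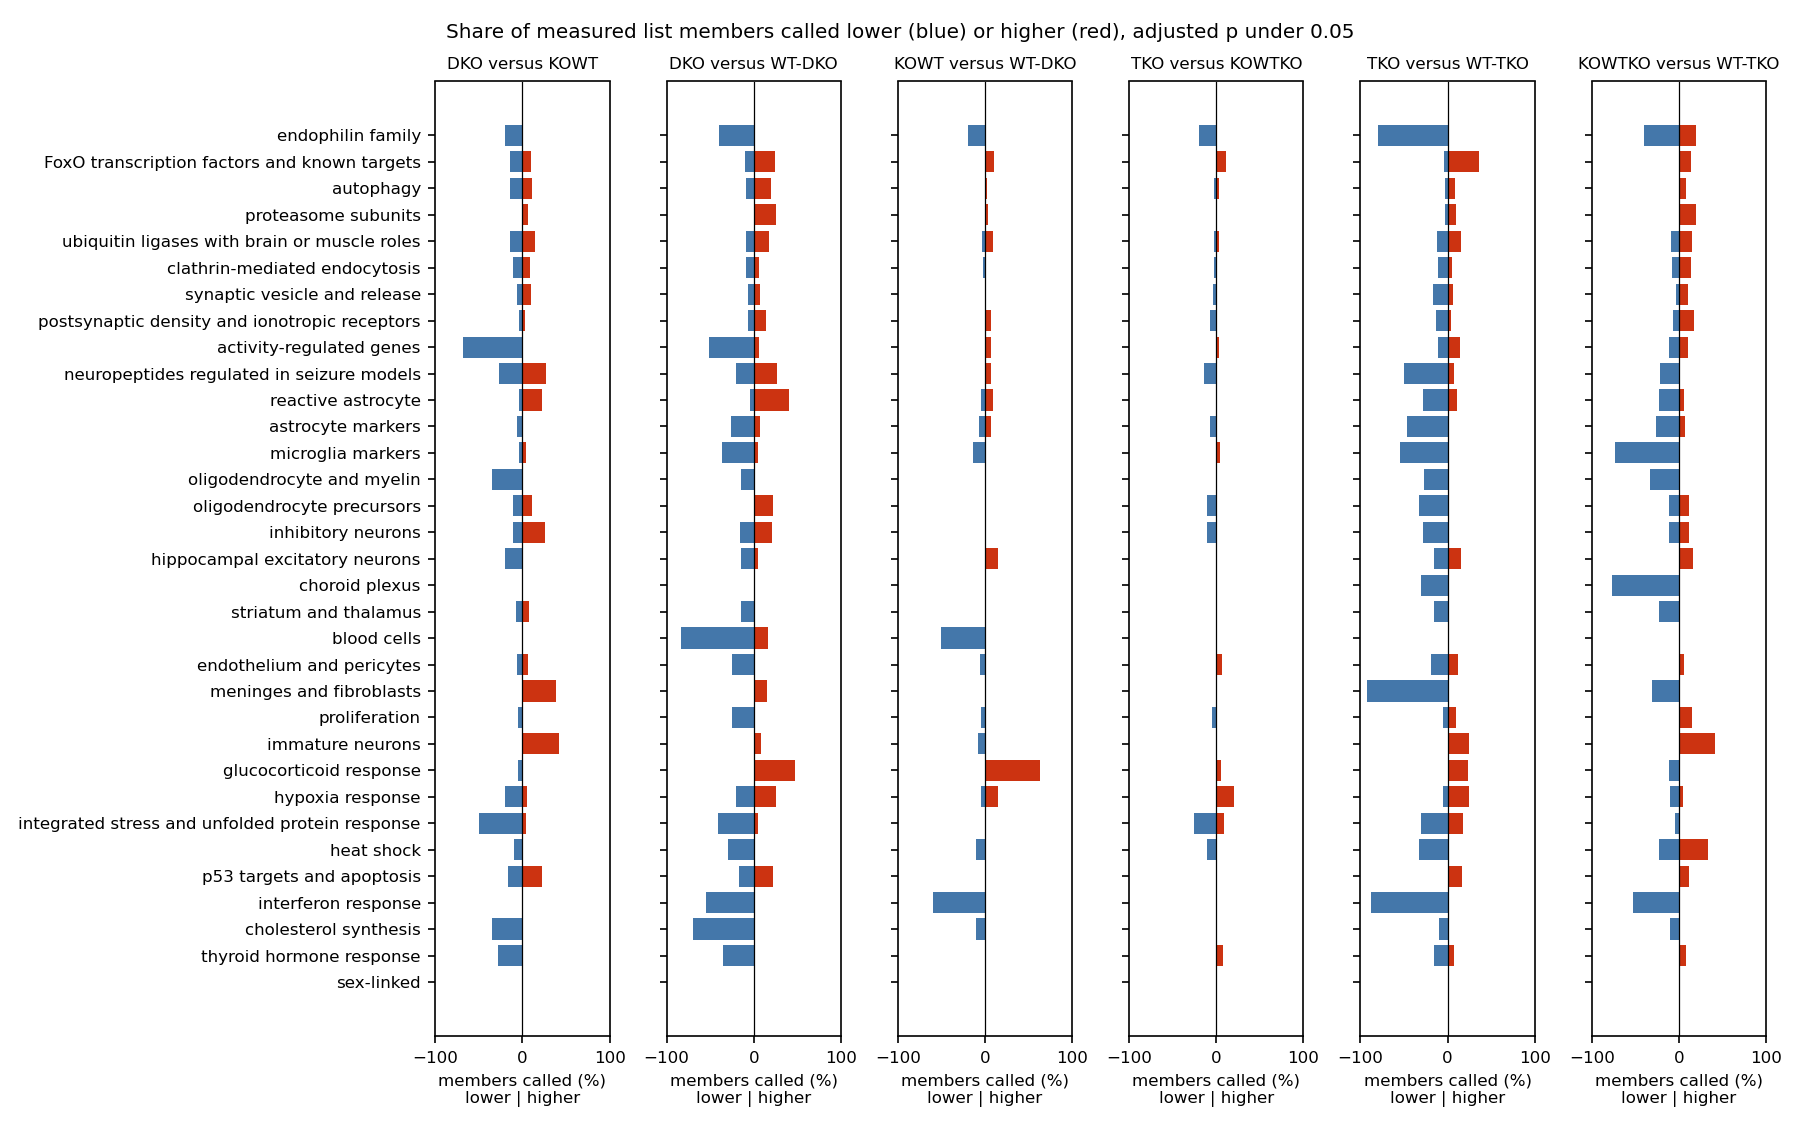
Percent of measured members of each of the 33 gene lists called higher (red, to the right) or lower (blue, to the left) in the 6 comparisons, at an adjusted p under 0.05. In DKO versus KOWT 21 of 31 activity-regulated genes are lower.

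Some of the same genes were called in both mutants. Among 15204 genes tested at both ages, 561 rose in both mutants against wild types (218 for independent lists) and 590 fell (247), with one-sided Fisher's exact p of 5.44e-120 and 2.45e-111; 144 went opposite ways (465). Against littermates, 94 rose in both (38.9; Fisher's exact p = 1.68e-16) and 77 fell (44.7; p = 1.18e-06), and 47 went opposite ways (83.5). Littermate groups, in which Sh3gl1 was present, also differed from these wild types (711 calls in KOWT, 3288 in KOWTKO). The overlap against wild types therefore cannot be credited to loss of Sh3gl1 alone. Log2 fold changes of the 2 ages correlated weakly against littermates (Spearman 0.114, against 0.350 with wild types). Fisher's test also takes genes as independent, which co-regulated genes are not. In all 4 comparisons of a mutant, 43 genes rose and 48 fell, where each mutant's libraries entered 2 comparisons. After Sh3gl1, Mpnd and Stap2, these were led by Uvssa, a DNA repair gene (log2 fold change 0.60 ± 0.10 in DKO and 0.43 ± 0.06 in TKO against littermates), and Pars2, the mitochondrial prolyl-tRNA synthetase (0.48 ± 0.07 and 0.32 ± 0.08), which rose. The heat shock protein gene Hsph1 (-0.83 ± 0.08 and -0.32 ± 0.05), the pentose phosphate enzyme gene Rpe (-0.43 ± 0.08 and -0.38 ± 0.08), the oligoribonuclease gene Rexo2 (-0.30 ± 0.05 and -0.32 ± 0.07), the dynein light chain gene Dynll1 (-0.29 ± 0.07 and -0.37 ± 0.07) and the histone gene Hist3h2a (-0.43 ± 0.08 and -0.31 ± 0.07) fell. The call of Dynll1 in DKO versus KOWT ended without the libraries low in Sh3gl3 (-0.24).

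The effects of the mutations differed between the ages for 1698 of 16805 genes against wild types and 1496 against littermates, a test that cannot separate age from the added loss of Sh3gl3. This test was not repeated without the libraries that stood apart. Against littermates, Fbxo32 differed by -0.71 on the log2 scale (DKO effect minus TKO effect), Fos by -1.87 and Arc by -1.62. The 1496 became 883 with no filter on low counts, and the 171 genes called the same way against littermates became 100 with no filter and 262 with DESeq2.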

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

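Tests around Sh3gl2, of Mpnd and of excitatory neuron markers were chosen only after the results were seen; those around Sh3gl1, and of the covariates for the activity-regulated genes, were stated before their results were seen, although total call counts under those covariates were known.

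Values per group of 4 to 10 libraries were checked for a highest or lowest library whose gap to the nearest other was large against the range of the group. Of 327 groups of values, 41 passed Dixon's 95% value, and chance alone passes about 1 in 20. In KOWT, replicate 6 was low for Gjb1 (ratio of gap to range 0.611) and Wsb2-ps (0.892), and replicate 4 for Serpina3f (0.851) and Serpina3m (0.873). In DKO, replicate 6 was high for Iyd (0.635), and replicate 5 low for Rps13-ps1 (0.819), Rps15a-ps8 (0.806), Serpina3f (0.779) and Serpina3m (0.719). In WT-DKO, replicate 3 was high for BC002163 (0.803) and low for Ndufs5 (0.654), replicate 4 high for Serpina3f (0.682) and Serpina3m (0.764), replicate 5 high for Cx3cr1 (0.467), replicate 9 high for Sgk1 (0.498) and replicate 10 low for Eps8l1 (0.536). Reads on genes were highest in WT-DKO replicate 8 (0.536), at 57.0 M. In WT-TKO, replicate 8 was high for Fbxo32 (0.548), Pdyn (0.613), Rps13-ps1 (0.905), Rps15a-ps8 (0.630) and Trem2 (0.580), replicate 7 for Cldn2 (0.666) and Slc4a5 (0.705), replicate 2 for Foxo3 (0.674) and replicate 1 for Scand1 (0.604). In KOWTKO, replicate 3 was low for Sh3gl1 (0.721) and Mpnd (0.747) and high for Stap2 (0.738). Replicate 7 was low for Irf9 (0.551), Kcna5 (0.553), Piezo2 (0.608) and Rpe (0.573), high for Pdk4 (0.648), and high for reads without a feature (0.563) and alignments that were not unique (0.707). Replicate 4 was high for Lgals3bp (0.696) and replicate 6 low for Sst (0.559). In TKO, replicate 8 was low for Crh (0.511) and replicate 4 for Rps13-ps1 (0.928) and Rps15a-ps8 (0.952).

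Effects that differed between the ages were found with edgeR's quasi-likelihood test for 52 of 109 named differences. Most named genes were picked for large changes or small p in a comparison entering the difference, so a high share follows from the choice. Over all 16805 genes, 1698 differed against wild types and 1496 against littermates. Meningeal genes mark tissue outside the hippocampus and varied widely between WT-TKO libraries, so their differences need not be effects of the mutations. Values are log2 fold changes in DKO minus those in TKO. Differences against wild types include WT-TKO replicate 8, which stood apart for Mbp and Pdyn. They were not tested again without it, so how far they depend on that library is open. Against wild types, the effect was higher in DKO for the meningeal and barrier genes Aldh1a2 (3.07), Col1a1 (3.11), Slc22a6 (3.49), Cldn11 (3.12) and Ptgds (4.91). The same held for the astrocyte genes Gfap (1.35) and Aspg (2.82), and the microglial and interferon genes Aif1 (1.10), Tmem119 (1.15) and Ifi27 (0.84). The effect was also higher for Nfkbia (0.44), Sgk1 (1.07), Npy (0.63), Pdyn (0.94), Sh3gl3 (7.72), Tpm3-rs7 (3.45), Wsb2-ps (3.17) and Serpina3f (3.40), whose size depended on WT-DKO replicate 4. It was lower for Fbxo32 (-0.77), Foxo3 (-0.39), Hbb-bt (-2.02), Hsph1 (-0.40), Iyd (-2.01) and Ren1 (-2.46). Against littermates, it was lower in DKO for the activity-regulated genes Arc (-1.62), Bdnf (-0.50), Fos (-1.87), Fosb (-2.77), Fosl2 (-0.74) and Homer1 (-0.52), the FoxO genes Fbxo32 (-0.71), Foxo3 (-0.25), Ccng2 (-0.82) and Pdk4 (-0.66), and Acer2 (-1.06), Dio2 (-0.89), Fam107a (-1.07), Gpr155 (-0.50), Hsph1 (-0.51), Kcna5 (-1.13), Msmo1 (-0.72), Stbd1 (-1.56), Sult1a1 (-1.71) and Trf (-1.25). It was higher for Arhgap36 (1.24), Col6a1 (1.90), Lhx6 (0.43), Lsp1 (1.10), Npy (0.74), Shank3 (0.44), Slc2a4 (1.11) and Scand1 (2.41), whose size depended on KOWTKO replicate 1.

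Activity-regulated genes fell in DKO versus KOWT in 21 of 31 members and in DKO versus WT-DKO in 16, where 2 rose, while 2 rose in KOWT versus WT-DKO. Of those 21, 21 stayed called with the choroid plexus mean as a covariate, 17 with the myelin mean as a proxy of age and 21 with the Xist level, with medians of -0.72 in each fit, as without a covariate, and interquartile ranges of 0.61, 0.48 and 0.61 against 0.63. The 20 excitatory neuron markers, some of them called lower, had a median of -0.10 (interquartile range 0.35). The 21 were chosen for their fall, which favours them in this comparison of medians. Without the libraries low in Sh3gl3, all 31 members, not chosen by their fall, had a median of -0.70 and the 20 markers -0.10. As far as these measures reach, the values argue against choroid plexus RNA, the age proxy, sex or fewer excitatory neurons as the whole cause. In the same fit 19 of the 21 stayed called, with a median of -0.81. At day 0, loss of Sh3gl1 in TKO versus KOWTKO came with 1 of 28 members higher, 0 lower and 27 not called (median -0.061, camera adjusted p = 0.339). An effect of losing Sh3gl1 on neuronal activity may underlie the pattern in the older samples, but it was not tested, and these data cannot separate it from handling or time of dissection.

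Calls clustered near Sh3gl2 in KOWT versus WT-DKO, where 14 of 44 genes tested within 10 Mb were called against 4.33% elsewhere (one-sided Fisher's exact p = 3.1e-09), which is consistent with variants of another strain carried with the targeted allele. Around Sh3gl1 the share was 34 of 144 genes in DKO versus KOWT (one-sided Fisher's exact p = 0.224) and 7 of 139 in TKO versus KOWTKO (p = 0.563 in the same test). That leaves the same explanation open there. The targeted genes, Stap2 and Mpnd were left out of all these counts. Mpnd lost 1.12 CPM per CPM of Sh3gl1 lost in DKO versus KOWT (64.0 and 56.9 CPM, an excess of 1.97 SE) and 1.03 in TKO versus KOWTKO (70.7 and 68.5 CPM), but annotated exons of Mpnd share 41 of the 5012 exon bases of Sh3gl1, so reads from the annotated overlap would have to be far denser there than elsewhere on Sh3gl1 to account for its fall. Coverage along Sh3gl1, transcripts beyond the annotated ends, a strain variant and an effect on Mpnd itself were not tested.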

How the results depend on the processing

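Alternatives that left out 7 libraries, used Xist or choroid plexus genes as a covariate, or kept only protein-coding genes were chosen after seeing the data. In DKO versus KOWT, 3347 calls became 2228 with only both groups in the fit, 2028 with the age proxy and 1082 without the libraries low in Sh3gl3. The first and last used fewer samples; the cause of the other was not tested. In TKO versus KOWTKO, 800 became 483 with no filter on low counts, which tests more genes, and 1306 with DESeq2, whose false calls were also more frequent in simulation (10.7% against 3.24%). The simulation drew once from dispersions estimated by edgeR, so it does not say whether the added DESeq2 calls were false. No filter also took the difference between ages against littermates from 1496 to 883 and the shared calls from 171 to 100, which DESeq2 took to 262. Leaving out 1 library gave 330 to 1444 calls in TKO versus KOWTKO and 470 to 811 in KOWT versus WT-DKO. The 1444 came without KOWTKO replicate 7, the newborn library with the most reads without a feature. Lists called numbered 11, 11, 12, 13, 11 and 9 in the 6 comparisons in the order reported, and with an estimated correlation 1, 1, 2, 1, 1 and 1, the endophilin list in each and the glucocorticoid list in KOWT versus WT-DKO. The endophilin list holds the targeted genes, and with an estimated correlation no other list was called in any comparison of a mutant. Fry called 6 in TKO versus KOWTKO and 5 in KOWTKO versus WT-TKO. Uncalled genes changed sign near 0: Sh3gl2 in DKO versus KOWT (-0.034), Sh3gl3 in DKO versus WT-DKO (0.015) and Fbxo32 in KOWT versus WT-DKO (-0.015) with the age proxy, Sh3gl3 in TKO versus KOWTKO with limma-voom (0.018), and Sh3gl1 in KOWTKO versus WT-TKO with DESeq2 size factors (0.0040), DESeq2 (0.0064) and the choroid plexus mean (0.012). The causes of these sign changes were not tested. Replicate numbers were not taken to pair the samples, since no 2 groups had every same-numbered pair correlated over 0.1. For KOWT and DKO the mean correlation was 0.228 against -0.0367 for other numbers, the lowest was 0.00583, 4 of 7 pairs were over 0.1 and 4 of 7 correlated best with their own number, a hint from the data and not from the design. With the replicate block, calls were 2955, 3081, 535, 553, 3219 and 2856. Among named genes the block ended calls of Serpina3m (4.29) and Serpina3f (3.71) in KOWT versus WT-DKO, Mir5105 (-1.29) and Pcsk1n (-0.88) in TKO versus KOWTKO, Tpm3-rs7 in TKO versus WT-TKO (-1.97) and KOWTKO versus WT-TKO (-1.90), and Rpl3-ps1 (-2.38) and Rn7sk (1.42) in KOWTKO versus WT-TKO. Of 172 named calls, 162 held in every fit that left out 1 library. Of 2088 values of named genes under an alternative, 2007 kept direction and side of the threshold. Depth, 13.1 M reads in the shallowest library, limits genes near 0 CPM, such as the pseudogenes in wild types.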

Other observations

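The comparison of interferon with microglia means was chosen only after the list values were seen. The test of whether littermate groups showed the lower interferon genes was chosen, and its criterion then tightened to need an estimated correlation, only after the result was seen. That the split test of shared calls decides nothing was also settled only after its result was seen.

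Further lists fixed before the data were examined gave these results. Of 12 immature neuron genes, 5 rose in DKO versus KOWT, 6 when adjusted over the list alone (camera adjusted p = 0.0102; adjusted p = 0.5 with an estimated correlation), and 1 rose without the libraries low in Sh3gl3. In KOWT versus WT-DKO 1 of the 12 fell, 5 when adjusted over the list alone (camera adjusted p = 0.00446; adjusted p = 0.354 with an estimated correlation), and in DKO versus WT-DKO 1 rose, also when adjusted over the list alone (camera adjusted p = 0.608), and 0 without the libraries that stood apart. In KOWTKO versus WT-TKO 5 rose, also when adjusted over the list alone (camera adjusted p = 0.0285; adjusted p = 0.727 with an estimated correlation), a call of the list that ended without WT-TKO replicate 8 and KOWTKO replicate 3. Of 6 blood cell genes, 5 fell and 1 rose in DKO versus WT-DKO, also when adjusted over the list alone (camera adjusted p = 0.00708; adjusted p = 0.419 with an estimated correlation), and 6 of 7 then measured fell and 0 rose without the libraries that stood apart. Of 31 proteasome subunit genes, 6 rose in KOWTKO versus WT-TKO, also when adjusted over the list alone (camera adjusted p = 0.000336; adjusted p = 0.727 with an estimated correlation), and the call of the list ended by fry. Of 15 astrocyte markers, 7 fell in TKO versus WT-TKO, also when adjusted over the list alone (camera adjusted p = 0.00645; adjusted p = 0.527 with an estimated correlation), a call of the list that ended without WT-TKO replicate 8 and KOWTKO replicate 3. Of 36 autophagy genes, 1 rose and 1 fell in TKO versus KOWTKO, 2 and 1 when adjusted over the list alone (camera adjusted p = 0.277), and 0 rose without WT-TKO replicate 8 and KOWTKO replicate 3. Of 36 genes of clathrin-mediated endocytosis, the process in which endophilin acts, 3 rose and 4 fell in DKO versus KOWT, also when adjusted over the list alone (camera adjusted p = 0.837), and 1 rose and 1 fell without the libraries low in Sh3gl3. In TKO versus KOWTKO 1 of the 36 fell, 0 when adjusted over the list alone (camera adjusted p = 0.0327; adjusted p = 0.472 with an estimated correlation), and the call of the list ended without WT-TKO replicate 8 and KOWTKO replicate 3. Of 29 FoxO factors and targets, the list chosen knowing the study topic, 3 rose in KOWT versus WT-DKO, 7 when adjusted over the list alone (camera adjusted p = 0.0132; adjusted p = 0.188 with an estimated correlation).

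Some genes, of which Hddc3, Tdg, Xist and Ddx3y were chosen after their values were seen, sat at separate levels within groups. Hddc3 (chromosome 7, 80343104 to 80350547) stood at 9.84, 9.43 and 8.65 CPM in KOWT replicates 4, 5 and 6 and at 7.81 and 7.21 in DKO replicates 5 and 6, the libraries low in Sh3gl3, against 30.8 to 36.7 in the other libraries of these groups, but it was also low, 8.21 to 10.4, in the WT-DKO libraries. Tdg stood at 1.98, 1.57 and 1.88 in those KOWT libraries and at 1.41 and 2.02 in those DKO libraries, against 7.29 to 10.03 in WT-DKO. In WT-TKO replicates 5 and 6, Hddc3 stood at 37.9 and 41.0 and Tdg at 2.295 and 2.232, and Tdg was likewise low in KOWTKO replicate 8 (2.26) and TKO replicate 9 (2.02). Sh3gl2 ranged from 10.9 to 28.5 CPM among TKO and KOWTKO libraries. Ttr ranged from 1.60 to 5845 CPM between libraries. WT-TKO replicate 8 held both Xist (206) and the Y-linked Ddx3y (47.9). Whether this library, KOWTKO replicate 3 and the libraries low in Sh3gl3 held mixed RNA or came from another genotype or strain was not settled by these values, and the means of their groups include them.

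The interferon list was lower, at the preset correlation, in all 4 groups with a targeted allele than in the separate wild types. The list fell in 2 of 2 comparisons of littermate controls with wild types, which restates the pattern, and with an estimated correlation it was called in 0 of the 4 groups (adjusted p = 0.366 for DKO, 0.188 for KOWT, 0.294 for TKO and 0.416 for KOWTKO). The interferon mean fell further than the microglia mean, by a log2 difference of -0.52 in DKO, -0.48 in KOWT and -0.48 in TKO. Exact two-sided permutation tests adjusted over 4 comparisons gave adjusted p = 0.0287, 0.0214 and 0.0460. In KOWTKO the difference was -0.20 (adjusted p = 0.382 in the same test). These values argue against fewer microglia as the whole cause in DKO and KOWT, although the comparison was chosen after the interferon fall was seen. TKO stayed undecided, as a covariate test there favoured fewer microglia by the criterion set beforehand. With the microglia mean as a covariate, 4 of the 15 members that fell in TKO versus WT-TKO stayed called, their median log2 fold change went from -1.05 (interquartile range 0.50) to -0.89 (0.53) and their median SE from 0.23 to 0.33, and the criterion set beforehand, which counted calls alone and favoured fewer microglia, was amended with these sizes after the result was seen. In TKO and KOWTKO a difference between the wild-type colony and the knockout lines cannot be told apart from fewer microglia. In all 4 groups that colony difference cannot be told apart from loss of Sh3gl2, which they shared and which was not tested.

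Among 100 splits of the libraries, the real one included, only 1, the real one, gave as many calls in DKO versus KOWT (3347, highest other 1403), DKO versus WT-DKO (4203, 831), KOWT versus WT-DKO (711, 115), TKO versus KOWTKO (800, 119), TKO versus WT-TKO (3595, 1779) and KOWTKO versus WT-TKO (3288, 245), and as many differences between ages against littermates (1496, 403). For these 7 counts no other split reached the real count, a share under the 0.05 set beforehand. Splits were drawn at random, and some can keep most of the real groups. Whether the highest others of 1403 and 1779 did so, or came from structure among the libraries, was not tested. The splits treat libraries as exchangeable, which the labels do not establish. Against wild types, 3 of 100 splits gave as many differences between ages (1698, highest other 2247), a share under 0.05. The real count was thus not the highest, and why another split exceeded it was not tested. For genes called the same way it was 1 of 100 against wild types (1151, highest other 0), against littermates (171, 0) and in all 4 comparisons of a mutant (91, 0). Shuffling breaks up the calls of every comparison at once, so that shared calls near 0 follow from how the splits were made. The criterion set beforehand, a share under 0.05, was therefore wrong for shared calls, and these splits say nothing about the overlap. Independent lists of the same sizes would share 218 rising and 247 falling genes against wild types, and 38.9 and 44.7 against littermates.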
